A study of Tursiops truncatus with 73 samples.

How the data were processed

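Blood RNA of wild bottlenose dolphins was measured on a custom Agilent array with 1 dye (Cy3), 4 arrays to a slide. Per the labels' protocols, blood was stabilised at collection, total RNA was extracted and checked for quality, and labelled RNA was made from it. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1, with the subtraction of local background switched off and the removal of spatial and multiplicative trends within each array switched on. The deposited files hold, per the file headers, the processed signal of each spot as an intensity on a linear scale, with no normalization between arrays. The deposited series table holds the same intensity values multiplied by a constant and rounded, since the ratio of the 2 lay between 995026 and 1004980 for all spots. Steps between the scanner files and any further analysis by the submitters are not given in the sources used here.

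Each of the 73 arrays held 45220 features, of which 1417 were controls and were left out. The 43803 remaining spots stood for 24418 distinct probes of 60 bases, 19242 of them with 2 or more spots, whose log2 values were averaged. None of the non-control spots was saturated (0 spots), and 380 probe values were missing. Gene symbols were those of the array design, carried in the files: 6249 probes had 1, giving 3827 symbols, and the symbols of 5192 probes were found in the reference table of the species (assembly mTurTru1.mat.Y). The other probes had no symbol, and 5588 of them were described only as unknown. The symbols are assignments made when the array was designed, and no genome was used here to check where a probe maps.

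The value analysed was log2 of the processed signal minus the 75th percentile of that array. Probes were kept when well above background on over 50% of the arrays of at least 1 location-by-sex group, which left 19169 probes, 5383 of them with a symbol, for 3444 genes. A probe's level is given relative to the 75th percentile of its array, so a negative value is a level below that percentile. Where a probe was not well above background in a group, or in all but 1 animal of it, the fold is a lower bound. It sets the brighter group's mean against the dimmer group's mean of, per animal, the higher of the probe's own value and the lowest well-above-background signal of the array. Of several probes of a gene, the one with the highest mean over all arrays stood for it. 1 male animal of Saint Joseph Bay had 2 arrays, which were averaged, so that 72 animals entered the tests. The titles of StJoseph_male replicate 1 and StJoseph_female replicate 7 hold the same animal code and differ in the sex label. They were counted as 2 animals, and whether they are 1 was not tested.

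Groups were taken from the labels: 5 locations and 2 sexes. The sample titles also hold a number that reads as a year (2005, 2006, 2009 or 2010) and is not labelled as one; it is called the title number. The linear models of limma 3.58.1 in R 4.3.3 (lmFit and eBayes) were fitted to all animals together, with Benjamini-Hochberg adjustment over the 19169 probes and a threshold of 0.05. Sexes were compared with location as a covariate and locations with sex as a covariate, each location having equal weight in a contrast. Further tests were a moderated F test over the 5 locations, the title numbers within Sarasota and within Saint Joseph Bay, and the difference of the sex effect between coasts. The word probe count means probes past the threshold unless another threshold is named.

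A set of 28 gene lists covering blood cell types, sex chromosomes, immunity and metabolism was tested with camera (limma) at its preset correlation of 0.01. The 22 lists with at least 5 measured genes were tested in 4 comparisons, and p was adjusted over these 88 pairs. The same lists were also tested with an estimated correlation and with fry. The named genes were chosen by a fixed rule. It took the 8 genes with the largest difference in each direction among those past the threshold, up to 3 genes of each list that camera called, and the measured Y-linked genes with KDM6A and EIF2S3 for the sexes. Where fewer than 5 genes passed, it took the 5 with the smallest p. CYP1A1, CYP1B1, AHR, AHRR, TIPARP, NQO1, XIST and DDX3X were also in the rule, and none of them was among the symbols of the kept probes. The comparisons, the gene lists, this rule and most alternatives were chosen before the data were examined.

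Alternatives covered quantile normalization, normexp background correction (offset 50), the filter on dim probes, the slide as a fixed or random block, the position on the slide, the series table, array weights, the handling of the animal with 2 arrays, blood cell list means as covariates, single sexes and single locations. Alternatives added after the data were seen were the scan day as a block, array brightness and detected share as covariates, the title number with the location as covariate, and fits without 4 arrays whose median correlation with the others was under 0.95 or without 6 animals described in the report, in all locations or within Sarasota and Saint Joseph Bay alone. The arrays lay on 19 slides that mixed locations, and were scanned on 6 days.

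The tests were tried on simulated data, in which 200 of the 19169 probes were changed, 100 by 0.5 and 100 by 1 on the log2 scale. For females against males, 77 of the 100 smaller and 97 of the 100 larger changes were recovered. The numbers were 75 and 96 for Atlantic against Gulf, 69 and 99 for Georgia against the other locations, and 35 and 81 for Brunswick against Sapelo. False calls numbered 9, 10, 8 and 4 in the same order. The simulated probes varied independently of one another, with no differences between slides, title numbers or locations beyond the changes made. The recovered shares need not hold for the real arrays.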

Results

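Blood transcripts of 72 wild bottlenose dolphins (Tursiops truncatus), 41 labelled female and 31 labelled male, were profiled on 73 arrays. The animals came from Beaufort (8 animals), Sapelo (13) and Brunswick (13) on the Atlantic coast and from Sarasota (19) and Saint Joseph Bay (19) on the Gulf coast. The series text counts 4 locations, and the labels hold 5, of which Sapelo and Brunswick both lie in Georgia. Beaufort had 2 males and the other location-by-sex groups had 6 to 12 animals. The 75th percentile of log2 signal ran from 7.48 to 10.25 across arrays, and 63.1% to 84.2% of spots were well above background. Sarasota arrays were the dimmest on average, at 8.45 ± 0.38 (SD, n = 19), and Brunswick arrays the brightest, at 9.16 ± 0.48 (SD, n = 13). The title number was 2006 for Beaufort and 2009 for both Georgia locations. Sarasota had 7 animals with 2005 and 12 with 2010, and Saint Joseph Bay 13 with 2005 and 6 with 2006.

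The sexes were compared to see which transcripts of blood differ between females and males. Several genes that lie on the X chromosome in other mammals were higher in animals labelled female. EIF2S3, a subunit of translation initiation factor 2, was higher by 0.73 on the log2 scale (SE 0.18), at 4.50 ± 0.88 (SD, n = 41) against 3.72 ± 0.80 (SD, n = 31). The deubiquitinase gene USP9X was higher by 0.44 (SE 0.05), with 39 of 41 females above the male mean. The histone demethylase gene KDM6A was higher by 0.46 (SE 0.11), the splicing factor gene ZRSR2 by 0.48 (SE 0.10), TXLNG by 0.45 (SE 0.07) and SYAP1 by 0.39 (SE 0.06).

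The probe named for EIF1AX, a translation initiation factor, went the opposite way, by -4.55 (SE 0.41). It stood at -6.84 ± 1.58 (SD, n = 41) in females and -2.26 ± 1.80 (SD, n = 31) in males, and it was well above background in 4 females and 28 males. Of these 4 females, 3 were among 6 animals described below, whose sex-linked probes went against their label. Without the 6 animals the EIF1AX probe was well above background in 1 of 38 females and 28 of 28 males, and at least 23.4-fold lower in females. It was among the probes used to pick out the 6, so its separation without them follows in part from that choice. The Y-linked ZFY, a zinc finger gene, was lower in females by a log2 difference of -0.33 (SE 0.06), and TM9SF3 by -0.20 (SE 0.04). Of 4 measured Y-linked genes, ZFY was the 1 that fell on the probe that stands for the gene, also when adjusted over the list alone, and it was well above background in 41 of 41 females. DDX3Y (-0.04, adjusted p = 0.887), SRY (0.46, adjusted p = 0.501) and USP9Y (0.22, adjusted p = 0.501) did not pass in limma, and these 3 were well above background in the 41 females too. Signal in females cannot come from a Y chromosome, so these probes and that of ZFY do not read Y-linked transcripts alone. Probes of one gene disagreed: a second USP9Y probe was lower in females by -1.46 (adjusted p = 6.9e-13), and 1 of 2 further USP9X probes passed at -1.95. Of 4 further TXLNG probes 2 rose and 1 fell. The latter was well above background in 3 of 41 females and 28 of 31 males, and 3.52-fold lower in females when bounded in the same way. Without the 6 animals it was so in 0 of 38 and 28 of 28, and at least 5.34-fold lower in females. This probe too was used to pick out the 6, so that separation follows in part from the choice.

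In limma, 43 of 19169 probes passed, 33 higher and 10 lower in females, and 15 of them differed by over 2-fold. A symbol was given for 15 of the 43, covering 10 genes, and 28 had none. The unnamed probe AM-20432, picked out after its values were seen, was well above background in 38 of 41 females and 3 of 31 males. On the 8 female-high and 4 male-high probes that differed by over 2.5, 6 animals lay with the other sex. They were 3 labelled female and 3 labelled male, 1 of each in Sarasota and 2 of each in Saint Joseph Bay. Without these 6 animals AM-20432 was well above background in 38 of 38 females and not well above background in any of 28 males, at least 529-fold higher in females (adjusted p = 6.1e-62), and 50 probes passed, including all 43. AM-20432 was among the probes that picked out the 6, so this separation and its p follow in part from that choice. Bounded in the same way over all animals, the fold was 173. With the slide as a block, 36 probes passed, and ZFY (adjusted p = 0.0734), EIF2S3 (adjusted p = 0.0626), KDM6A (adjusted p = 0.186), ZRSR2 (adjusted p = 0.210) and TM9SF3 (adjusted p = 0.210) did not. Within scan days, 90.7% to 100% of the 43 probes kept their direction, and within slides 9.30% to 100%, with under 50% on 2 of 18 slides. On those 2 slides the 1 female was among the 6 animals, and without the 6 the range was 79.1% to 100% over 16 slides. All these shares come from the animals that gave the calls, so they are no separate test.

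**Figure D1:**
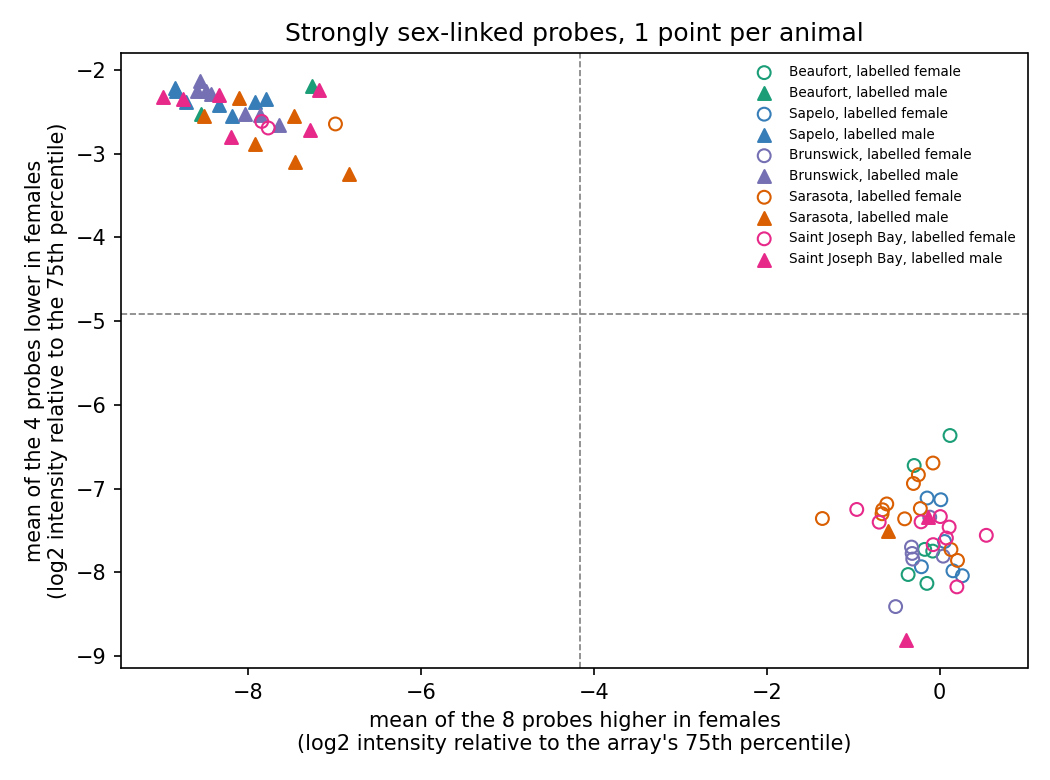
Each point is 1 animal, placed by its mean log2 intensity on the 8 probes strongly higher in females (horizontal) and on the 4 strongly lower in females (vertical), both relative to the 75th percentile of the array. Open circles are animals labelled female, filled triangles animals labelled male, colours give the location and dashed lines the midpoints between the sexes; 3 circles lie among the triangles and 3 triangles among the circles.

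Among the gene lists, X-linked genes that often escape inactivation stood out as higher in females. Of 13 measured genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.36 and a mean of -0.09, which differ in sign. The 1 that fell was EIF1AX. Without the 6 animals its probe was well above background in 28 of 28 males and 1 of 38 females. Its fall is therefore a value of that probe and is not shown to be one of the X-linked gene. Camera gave an adjusted p of 1.1e-06 for a rise, and an adjusted p of 1.3e-05 with an estimated correlation. With the slide as a block the adjusted p in camera was 0.000187, and the list's median lay above that of all probes on all 6 scan days, by 0.16 to 0.48, and on 16 of 18 slides. Shifts of lists within scan days and slides, here and below, come from the animals that gave the calls and are no separate test. Taking the mean of all probes of a gene instead of 1 probe gave an adjusted p of 0.977 in camera.

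Ribosomal protein genes were shifted up in females as a list, with a median of 0.24, although none of the 72 genes passed alone (0 also adjusted over the list alone). Camera gave an adjusted p of 5.7e-17 for the ribosomal list, and an adjusted p of 0.99 with an estimated correlation. Heat shock and unfolded protein genes were shifted down (median -0.10, adjusted p = 0.000134), and erythroid (median 0.22, adjusted p = 0.0424) and oxidative phosphorylation genes (median 0.07, adjusted p = 0.0173) up. Each of these 3 lists had an adjusted p of 0.99 with an estimated correlation, and 0 of their 28, 9 and 69 genes passed. The ribosomal shift was upward on 4 of 6 scan days and 15 of 18 slides, the oxidative phosphorylation shift on 4 and 13, and the erythroid shift on 5 and 14. The heat shock shift was downward on 5 of 6 scan days and 11 of 18 slides. With the slide as a block the adjusted p was 2.5e-09 for the ribosomal, 0.000283 for the heat shock, 0.0053 for the oxidative phosphorylation and 0.0584 for the erythroid list. Female arrays were dimmer on average, at 8.81 ± 0.56 (SD, n = 41) against 8.97 ± 0.55 (SD, n = 31) for the 75th percentile.

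The coasts were compared because the animals were sampled at different places. The mitochondrial gene MT-ND1, which encodes a subunit of respiratory complex I, gave the largest difference among the named genes, lower in Atlantic animals by a log2 difference of -5.27 (SE 0.21). Its probe stood at -5.45 ± 0.57 (SD, n = 34) in Atlantic and at -0.21 ± 1.12 (SD, n = 38) in Gulf animals, well above background in 25 and 38 of them, and it was lower in Atlantic animals on 18 of 18 slides. The 3 Atlantic locations were alike, at -5.73 ± 0.56 in Beaufort (SD, n = 8), -5.29 ± 0.51 in Sapelo (SD, n = 13) and -5.44 ± 0.62 in Brunswick (SD, n = 13). Several other mitochondrial genes were higher in Atlantic animals on average: MT-ATP8, a subunit of ATP synthase, by 1.09 (SE 0.19), MT-ATP6 by 0.65 and 0.61 on 2 of its 3 probes (the third did not pass, at -0.27, adjusted p = 0.0561), MT-ND6 by 0.51 and MT-ND4 by 0.35. On MT-ATP8, Sarasota (2.56 ± 1.04, SD, n = 19, from -0.19 to 3.59) lay near Beaufort (2.76 ± 0.49, SD, n = 8, from 1.89 to 3.46). Saint Joseph Bay was lower, at 1.65 ± 1.01 (SD, n = 19), so not every Gulf animal was lower on this gene.

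The 2 probes of MT-ND2 differed: AM-3764 was well above background in 0 of 34 Atlantic and 29 of 38 Gulf animals, at least 2.52-fold lower in Atlantic animals (adjusted p = 2.8e-13), and AM-30339 did not pass (-0.15, adjusted p = 0.399). MT-CO3 was higher on 2 probes (0.64 and 0.40) and lower on the third (-0.63). MT-CYB (-0.28, adjusted p = 0.276) and MT-CO1 (-0.12, adjusted p = 0.776) did not pass. Of the 9 measured mitochondrially encoded genes, 5 rose and 1 fell, over all probes and adjusted over the list alone, and the list's median (0.35) and mean (-0.32) differ in sign.

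**Figure D2:**
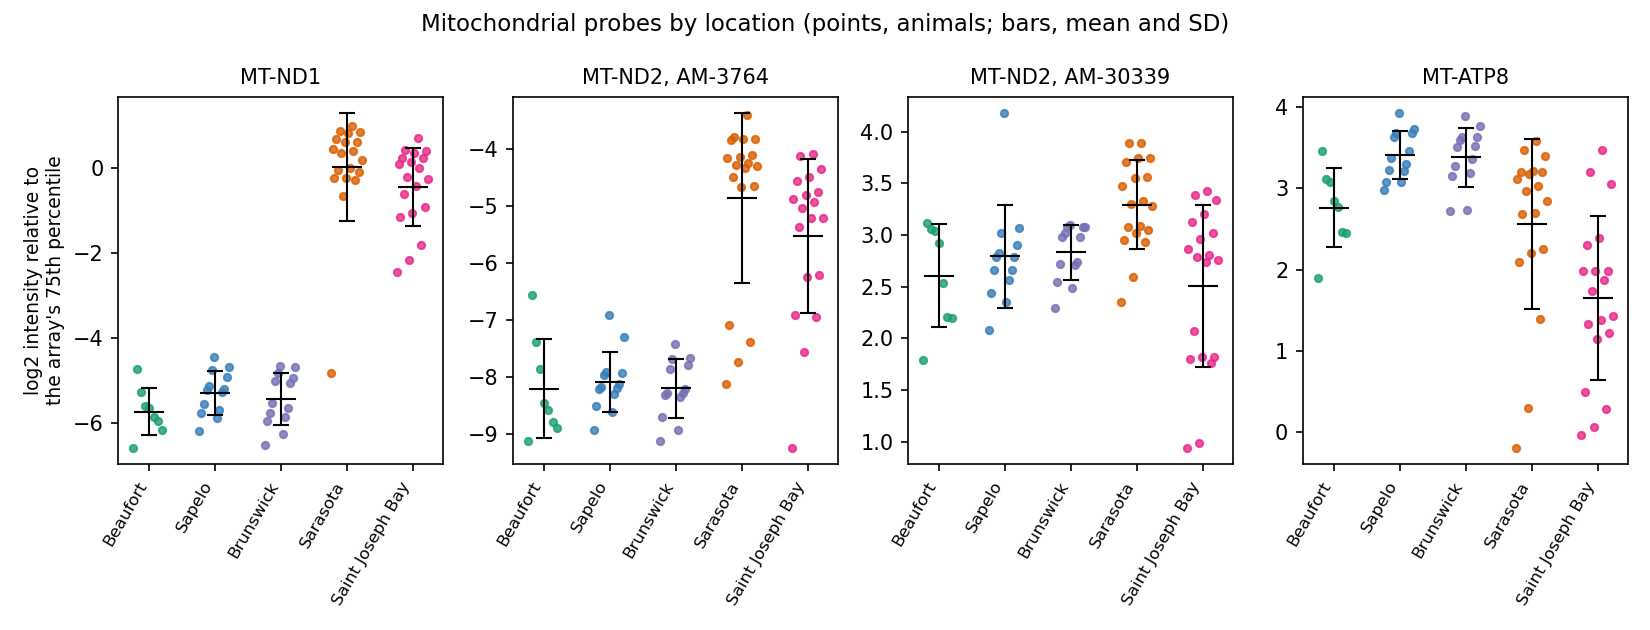
Levels of 4 mitochondrial probes (log2 intensity relative to the 75th percentile of the array) are shown by location, with 1 point per animal and bars for the mean and SD. On the MT-ND1 probe 1 Sarasota animal (Sarasota_female replicate 12, one of the 6 against their sex label) lies among the Atlantic values, and on the MT-ND2 probe AM-3764 several animals of both Gulf locations do, where the Atlantic values are not well above background (0 of 34 animals).

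Among nuclear genes, AK1, an adenylate kinase that balances adenine nucleotides, was higher in Atlantic animals by 1.94 (SE 0.38), at 2.16 ± 0.99 (SD, n = 34) against 0.32 ± 2.10 (SD, n = 38). RGS1, which limits G-protein signalling, was higher by 0.82 (SE 0.20), and GVIN1, an interferon-induced GTPase, by 0.69 (SE 0.14), with its 4 other probes higher as well (0.75 to 0.88). CKM (0.76), FER (0.73), DCN (0.72) and RPAP2 (0.71) were also higher. The red cell water channel gene AQP1 was lower by -1.02 (SE 0.29), the globin gene HBE1 by -0.83 (SE 0.30), and NCOA4, which directs ferritin to breakdown, by -0.80 (SE 0.20). The erythroid list as a whole was not called for the coasts. Its mean was 3.22 to 3.49 in the Atlantic locations, 3.07 in Saint Joseph Bay animals titled 2005 and 3.47 to 4.01 in the other Gulf animals. RTN3 (-1.87), RND3 (-0.87), ANG1 (-0.85) and the ribosomal protein gene RPL36A (-0.79) were also lower. RPL36A stood at 7.54 in Sarasota, while Saint Joseph Bay (5.76) lay between Brunswick (5.72) and Sapelo (5.82). The 3 Atlantic means lay on the same side of both Gulf means in 15 of the 21 named genes, and did not in RGS1, RPL36A, RPS21, RPL36, ATP5I and NDUFB3. These genes were picked for their coast difference in the same animals, which favours such a parting in advance. In limma 4774 probes passed, 2909 higher and 1865 lower, which is 24.9% of the probes, with a median size of 0.33, and 50 of them differed by over 2-fold.

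Among ribosomal protein and oxidative phosphorylation genes, most did not pass between the coasts, and most of those that passed fell in Atlantic animals. Of 72 ribosomal protein genes, 9 fell (7 adjusted over the list alone) and 0 rose, with a median of -0.23, among them RPL36A, RPS21 (-0.37) and RPL36 (-0.32). Camera gave an adjusted p of 0.000119 for the ribosomal list, and an adjusted p of 0.99 with an estimated correlation. Of 69 oxidative phosphorylation genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.12, among them ATP5I (-0.52), NDUFA2 (-0.36) and NDUFB3 (-0.37). That list had an adjusted p of 0.00156, and an adjusted p of 0.99 with an estimated correlation. These were not clear differences shared by all locations of a coast. NDUFA2, though its Atlantic means lay on the same side of both Gulf means, was nearly equal in Beaufort (-3.80) and Saint Joseph Bay (-3.79). NDUFB3 was higher in Beaufort (0.56) than in Saint Joseph Bay (0.51). The mean of the ribosomal list was 5.98 in Beaufort against 5.34 in the Saint Joseph Bay animals titled 2005 and 6.15 in those titled 2006, the title number of Beaufort. That of the oxidative phosphorylation list was 1.77 in Beaufort against 1.52 and 1.83. Of 12 interferon-stimulated genes 3 rose (4 adjusted over the list alone), with an adjusted p of 0.0598 in camera. None of the 18 xenobiotic metabolism and AhR genes passed (0, also adjusted over the list alone), with an adjusted p of 0.820 in camera.

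The Atlantic arrays were brighter, at 9.05 ± 0.55 (SD, n = 34) against 8.72 ± 0.52 (SD, n = 38), and had more spots above background, 77.50% against 74.96%. With both measures as covariates 3547 probes passed, 3092 of the 4774 among them; AQP1 (-0.54, adjusted p = 0.0673), HBE1 (-0.45, adjusted p = 0.223), RPL36A (-0.51, adjusted p = 0.0523), RPS21 (-0.18, adjusted p = 0.0567), RPL36 (-0.14, adjusted p = 0.209) and CKM (0.65, adjusted p = 0.0756) did not. The ribosomal list had an adjusted p of 0.488 and the oxidative phosphorylation list an adjusted p of 0.0189 in that fit. With the slide as a block 3531 probes passed, and CKM (adjusted p = 0.146) and HBE1 (adjusted p = 0.0564) did not. The adjusted p of the ribosomal list was then 3.6e-06 and that of the oxidative phosphorylation list 0.00266. Between 66.4% and 99.02% of the 4774 probes kept their direction within each of 5 scan days, and 53.6% to 93.8% within each of 18 slides. The same animals gave the calls, which favours high shares in advance, so these are no separate test. The ribosomal list was lower on 5 of 5 scan days and 12 of 18 slides, and the oxidative phosphorylation list on 4 and 12.

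Without Georgia, Beaufort differed from the Gulf locations in 1832 probes, and 1297 of the 4774 stayed past the threshold; females alone gave 1693 and males alone 600. Of 21 named genes, 5 kept their call without Georgia, 14 missed the threshold in the same direction and 2 turned, and the smaller number of animals was not separated from an effect of Georgia. MT-ND1 kept its size (-5.56, adjusted p = 5.7e-14), while RGS1 turned to -0.12 (adjusted p = 0.881) and RPL36 to 0.04 (adjusted p = 0.923). Among the 14 animals whose titles hold 2006, 995 probes passed; MT-ND1 differed by -5.55 (adjusted p = 2.3e-06), RGS1 by -0.69 (adjusted p = 0.327) and NDUFA2 by 0.21 (adjusted p = 0.584). In the 58 other animals, Georgia against the Gulf gave 5902 probes, and 2832 of them (48.0%) had the same direction among the 14.

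The Georgia locations were then set against the other 3 locations. RGS1 was higher in Georgia animals by 1.32 (SE 0.21), at -3.40 ± 0.87 (SD, n = 26) against -4.70 ± 0.83 (SD, n = 46). GBP5, an interferon-induced GTPase, was higher by 0.89 (SE 0.18) and HLA-DQA2, an MHC class II chain, by 0.76 (SE 0.13), the latter with 24 of 26 Georgia animals above the mean of the others. GOLGA4, which tethers vesicles at the Golgi, was higher by 0.74 (SE 0.12) in 26 of 26, and 11 of its 12 other probes rose. AK1 (1.15, but -0.25 against Beaufort alone, adjusted p = 0.834), MT-ATP8 (1.11), the retinal dehydrogenase gene ALDH1A1 (0.92) and RPGR (0.81) were higher too. MT-ND1 was lower by -3.29 (SE 0.23), a difference that was 0.40 (adjusted p = 0.491) against Beaufort alone. FCRL3, an Fc receptor-like gene of lymphocytes, was lower by -0.76 (SE 0.19), and ANG1 (-0.97), ATP10D (-0.87), AQP1 (-0.83), COX19 (-0.81) and S100A1 (-0.74) were lower. APM2 passed as lower (-0.77), but it was well above background in 10 of 26 Georgia animals and 23 of 46 others, and the highest animals of Sarasota (-1.13) and Saint Joseph Bay (-0.63) lay far above the means there (-5.94 and -5.64).

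The ribosomal protein and oxidative phosphorylation genes that passed for Georgia mostly fell. Of 72 ribosomal protein genes 37 fell and 0 rose (42 and 0 adjusted over the list alone), with a median of -0.36, among them RPL27 (-0.54), RPL36 (-0.52) and RPS21 (-0.52). Camera gave that list an adjusted p of 1.1e-06, and an adjusted p of 0.99 with an estimated correlation. Of 69 oxidative phosphorylation genes 31 fell and 2 rose (33 and 2 adjusted over the list alone), with a median of -0.24, among them ATP5I (-0.65), NDUFA2 (-0.51) and ATP5G1 (-0.57). Its adjusted p was 4.3e-05 in camera, 0.99 with an estimated correlation and 0.0115 in fry, which tests whether the genes of a list move one way. Of 9 mitochondrially encoded genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.41 and a mean of -0.08, which differ in sign (adjusted p = 0.416 in camera). Of 12 interferon-stimulated genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), with a median of -0.04 against a mean of 0.02 and an upward direction in camera (adjusted p = 0.669). Of 3 MHC class II presentation genes 0 rose and 1 fell (2 and 1 adjusted over the list alone), and of 6 B cell and plasma cell genes 0 rose and 1 fell (0 and 3 adjusted over the list alone). Of 19 oxidative stress defence genes 3 fell (3 adjusted over the list alone), with an adjusted p of 0.203 in camera and 0.00619 in fry. Of 18 xenobiotic metabolism and AhR genes 2 rose and 2 fell, also adjusted over the list alone, with a median of -0.09 and a mean of -0.02 against an upward direction in camera (adjusted p = 0.924).

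**Figure D3:**
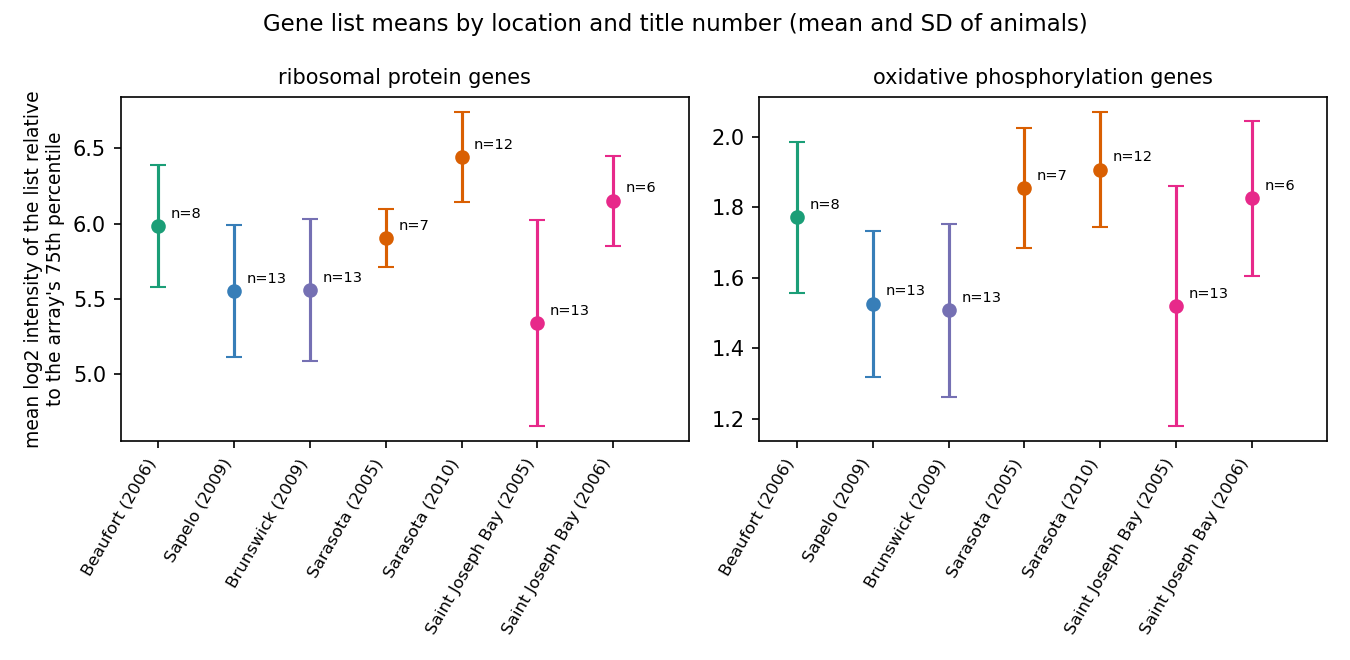
Mean log2 intensity of the ribosomal protein list (left) and the oxidative phosphorylation list (right), relative to the 75th percentile of the array, is given by location and title number as mean and SD over animals, with the number of animals beside each point. Ribosomal protein genes average 5.55 in Sapelo and 5.56 in Brunswick, between the 5.34 of Saint Joseph Bay animals with 2005 and the 6.44 of Sarasota animals with 2010.

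In limma 5136 probes passed for Georgia, 2883 higher and 2253 lower, and 59 of them differed by over 2-fold. Georgia arrays were brighter than the others, at 9.13 ± 0.47 (SD, n = 26) against 8.73 ± 0.56 (SD, n = 46). With brightness and detected share as covariates 3102 probes passed, and AQP1 (adjusted p = 0.530), S100A1 (adjusted p = 0.187) and COX19 (adjusted p = 0.0930) did not. The adjusted p of the list was then 0.0727 for ribosomal protein and 0.000369 for oxidative phosphorylation genes. With the slide as a block 4047 probes passed, with all 22 named results among them, and the adjusted p was 1.8e-09 for the ribosomal and 1.3e-05 for the oxidative phosphorylation list. Between 82.2% and 97.8% of the 5136 probes kept their direction within each of 5 scan days, and 74.2% to 91.0% within each of 15 slides. Here too the shares come from the animals that gave the calls and are no separate test. The ribosomal list was lower on 4 of 5 scan days and 11 of 15 slides, and the oxidative phosphorylation list on 5 and 10. Both Georgia locations hold only 2009 in their titles and no other location does, so location and title number cannot be told apart here.

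Brunswick and Sapelo, with the same title number, were compared to see how far neighbouring locations differ. Among the probes that stand for genes, that of the mitochondrial ribosome gene MRPS23 had the smallest p, with a difference of 0.56 (SE 0.17), at -0.33 ± 0.45 (SD, n = 13) in Brunswick and -0.89 ± 0.42 (SD, n = 13) in Sapelo. MOCS2 (-0.50, and -0.55 on its other probe), ZNF2 (-0.45), POM121 (-0.42) and RGS10 (0.38) came next. None of the 5 genes passed (adjusted p = 0.9998), and they are given as values. In limma 0 of 19169 probes passed and 2.31% had an unadjusted p under 0.05. No gene list was called by camera, and the smallest adjusted p was 0.172, for both the heat shock and unfolded protein and the proteasome genes.

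Over all 5 locations, 10066 probes passed the moderated F test of limma, which is 52.5% of the probes tested. A fit with the slide as a block gave 8651.

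Title numbers were compared within the 2 locations that hold a pair of them. Ribosomal protein genes averaged 6.44 ± 0.30 (SD, n = 12) in Sarasota animals with 2010 and 5.90 ± 0.19 (SD, n = 7) in those with 2005. In Saint Joseph Bay they averaged 6.15 ± 0.30 (SD, n = 6) in animals with 2006 and 5.34 ± 0.68 (SD, n = 13) in those with 2005. T cell genes (3 measured) averaged -1.35 ± 0.30 against -1.92 ± 0.35 in Sarasota and -1.79 ± 0.54 against -2.59 ± 0.56 in Saint Joseph Bay, each with the later number first (SD, same animals). Neutrophil genes averaged 1.12 ± 0.45 against 1.14 ± 0.36 and 0.87 ± 0.47 against 1.41 ± 0.40. The lists were not tested in these comparisons. In limma 2814 probes passed in Sarasota, 2175 higher and 639 lower with 2010, and 749 of them differed by over 2-fold. In Saint Joseph Bay 3143 passed, 1404 higher and 1739 lower with 2006, and 516 differed by over 2-fold. The numbers were 749 and 3625 with the slide as a block.

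The sex difference was compared between the coasts. For a difference in the sex effect 0 of 19169 probes passed in limma, 362 had an unadjusted p under 0.05, and 18 alternatives gave 0 to 6 probes.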

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

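The tests of mixed RNA, of the mitochondrial probes (both criteria for a sequence difference), of array brightness and of the splits of the 5 locations were chosen only after the result was seen, and the other tests were planned.

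The sex-linked probes of 6 animals went against the label: 3 labelled female looked male, and 3 labelled male looked female. On 35 other probes that differ by sex by less than 1 on the log2 scale, called without these animals, 6 of 6 lay nearer to the other label's mean, against 0 of the 66 others, on whom the probes had been chosen. RNA of another animal mixed in would raise both the female-high and the male-high probes, and 0 of 6 had both sets above the midpoint. An exchange with an animal of another location was left open, since 2 of the 6 lay nearest to another location's mean on 500 probes, both to an Atlantic one, while 9 of 32 other Gulf animals (28.1%) lay nearest to another location and 3 of them to an Atlantic one; another of the 6, Sarasota_female replicate 12, was the 1 Gulf animal with MT-ND1 (-4.83) below the highest Atlantic value (-4.45). Mislabelled or exchanged animals may therefore be the source, as a hypothesis, with as many animals going each way within Sarasota and within Saint Joseph Bay; no biological explanation was tested. StJoseph_male replicate 1, one of the 6, has the same animal code in its title as StJoseph_female replicate 7. Whether these are 1 animal was not tested.

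The probes of MT-ND1 and AM-3764 of MT-ND2 were lower in Atlantic animals. A lower mitochondrial transcript level would lower the other mitochondrial genes too, and their median difference was 0.40 (from -0.28 to 1.09 over 7 genes), which argues against it. A sequence difference under the probe was to part the Gulf animals by over 2 on AM-3764 alone; the widest gap was 1.11, with 1 animal below it that was not well above background, which decides nothing. A second criterion, set after that outcome was known, used the difference of the 2 MT-ND2 probes; its gap of 2.07 decides nothing either, since 0 of the 8 Gulf animals on the low side were well above background on AM-3764 and the gap was 0.41 with such values held at the lowest level counted as above background. In Sarasota, female replicates 3 and 9 and male replicate 3, all low on AM-3764, were also low on MT-ATP8 (0.29, 1.39 and -0.19, the others 2.09 or higher). On MT-CO1 they stood at -6.36, -5.68 and -7.95 (the others -3.80 or higher), and on AM-30339 at 3.02, 3.90 and 2.35. Sarasota_female replicate 12, low on AM-3764 too, was at 3.20 on MT-ATP8. In Saint Joseph Bay, male replicates 7 and 9 and female replicates 10 and 11, all titled 2006, were low on AM-3764. They were also lowest on MT-CO1, at -9.11, -6.08, -7.88 and -5.75 (the others there -5.48 or higher). On MT-ATP8 they stood at -0.03, 0.49, 1.34 and 1.98, where the others there ran from 0.07 to 3.48. Their AM-30339 values were 1.77, 3.39, 2.74 and 3.43. This pattern in both Gulf locations was seen after the fact and was not tested. A sequence difference stays open, as does a difference between the animals of the coasts, and no sequence was at hand to check it.

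The location differences covered many probes, mostly by small amounts, and the arrays, the blood and the title numbers differ between locations too. Array brightness as the whole cause is argued against, since 64.8% of the 4774 probes of the coast comparison kept their call with brightness and detected share as covariates. With the T cell, neutrophil and erythroid list means as covariates 98.2% kept it. That argues against blood cell makeup only as far as these 3 list means measure it, and other blood cell types were not covered. Whether what the title number stands for is part of the difference was not settled. In separate animals 48.0% of the probes called without 2006 had the same direction with 2006, against 48.3% of all probes. That share lay within the 26.4% to 80.1% of 99 relabellings of the 14 animals, 55 of which gave a share as large. The animals without 2006 set Georgia against the Gulf, and those with 2006 set Beaufort against Saint Joseph Bay. Differences peculiar to single locations would leave the same value, so it cannot decide. The rule written beforehand counted a share such as the 83.2% that kept their direction among titles with 2006 against the title number. That share is held here to decide nothing, since those 14 animals were also among the 72 that gave the calls. Georgia shares its title number with 0 other locations, so for its 5136 probes location and title number cannot be told apart, and a difference between the animals of the locations stays open, untested.

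For the count of 43 probes between the sexes, 2 of 100 splits called as many, the real one included (highest other 559). That share is under 0.05, but another split called several times as many, so chance is unlikely for the count rather than excluded. What set that split apart was not examined. The splits for the locations shuffled single animals among locations within each sex. They ask whether the locations differ at all, and not whether the coasts or Georgia differ as such. A chance allocation of animals to locations is unlikely for the counts of the coasts (real 4774, 1 of 100 splits, highest other 2), of Georgia (real 5136, 1 of 100, highest other 939) and of the 5 locations (real 10066, 1 of 100, highest other 20). For the title numbers of Sarasota (real 2814, 2 of 100 splits, highest other 2947) and Saint Joseph Bay (real 3143, 2 of 100, highest other 3225), chance is unlikely rather than excluded. In each, another split called more, and 11 and 20 of the other splits called any probes. Chance cannot be excluded for Brunswick against Sapelo (real 0 in limma, 2.31% at an unadjusted p under 0.05, 100 of 100 splits, highest other 482) or for the sex difference between coasts (real 0 in limma, 362 at an unadjusted p under 0.05, 100 of 100, highest other 714). Every split calls at least 0 probes, so these shares of 100 of 100 were fixed in advance and decide nothing. With the location as the unit the splits are too few: of 10 ways to set 2 locations against 3, 2 called as many probes as the coasts (real 4774), the highest other being the Georgia pair with 5136, and Beaufort with Saint Joseph Bay called 4761.

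Single animals lay far from the rest of their location-by-sex group on some sex-linked genes, the gap to the nearest animal being large against the range of the group, which chance gives in about 1 of 20 groups. EIF1AX stood at -7.48 in Sarasota_male replicate 6, one of the 6 animals above, with the nearest at -1.99. TXLNG stood at -0.27 in Sapelo_female replicate 1 (nearest -0.73) and at -0.35 in Brunswick_female replicate 5 (nearest -0.72). ZFY stood at -4.21 in Beaufort_female replicate 5 (nearest -3.80) and at -3.38 in Sarasota_male replicate 7 (nearest -3.70). TM9SF3 stood at -1.26 in Brunswick_male replicate 5 (nearest -1.11). These are 6 of 84 gene-by-group sets of the sex comparison (7.14%), near the share that chance gives. Such an animal was found in 9 of 147 gene-by-group sets of the named genes of the coast comparison, in 6 of 154 of the Georgia comparison and in 1 of 35 of Brunswick against Sapelo. The sets did not cover every location-by-sex group. Sarasota_female replicate 12, also one of the 6 animals against their sex label, is not counted in them, with EIF1AX at -1.85 (nearest -6.42).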

How the results depend on the processing

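The fits with the scan day, array brightness, the title number as a covariate, and without the 4 least correlated arrays or the 6 animals against their sex label were chosen only after the result was seen; causes of the changes were not tested unless one is named.

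Of 27 alternatives for the sexes (main 43), 19 stayed within 1.5 times; normexp background correction gave 22 probes, Beaufort alone 11, Sapelo alone 20, Brunswick alone 23, Sarasota alone 2 and Saint Joseph Bay alone 0 in limma (678 at an unadjusted p under 0.05). The 6 animals against their sex label are all from Sarasota and Saint Joseph Bay, and without them these locations alone gave 16 and 15. DDX3Y, which did not pass, turned to 0.0086 without the 6 animals and to 0.053 in Sarasota alone (0.087 without the 6, and 0.094 in Saint Joseph Bay alone without the 6), and USP9Y to -0.18 in Saint Joseph Bay alone.

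For the coasts (main 4774), 17 of 24 alternatives stayed so; the others were normexp 1040, array weights 7586, without the 4 least correlated arrays 7162, only titles with 2006 995, without Georgia 1832, females only 1693 and males only 600. The share of higher probes was 60.9% in the main test, 48.8% with array weights, 48.6% without those 4 arrays, 49.5% with no filter and 77.6% with 2006 alone. CKM turned to -0.063 with normexp, RGS1 to -0.69 with 2006 alone and to -0.12 without Georgia, NDUFA2 to 0.21 with 2006 alone and RPL36 to 0.039 without Georgia.

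For Georgia (main 5136), 18 of 25 stayed so; the others were normexp 1656, no filter on dim probes 8412, brightness covariates 3102, against Beaufort alone 3247, against Sarasota alone 8217, females only 2438 and males only 2000. Against Beaufort alone AK1 turned to -0.25 and MT-ND1 to 0.40. Higher probes made up 56.1% in the main test and 36.5% with no filter.

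Brunswick against Sapelo (main 0) gave 2 probes with array weights and 0 in limma in 19 other alternatives; ZNF2 (0.14) and POM121 (0.11), which did not pass, turned with normexp. The test over the 5 locations (main 10066) gave 5081 with normexp and 6503 with brightness covariates.

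The title numbers of Sarasota (main 2814) gave 1837 with quantile normalization, 586 with normexp, 749 with the slide as a fixed block and 5237 with blood cell list means. Those of Saint Joseph Bay (main 3143) gave 1269 with normexp, 1944 with array weights, 1022 with blood cell list means and 1533 without the 4 arrays. Normexp moved the median of all probes to 0.21 in Sarasota (main 0.05) and to -0.12 in the sex difference between coasts (main -0.04).

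The sex difference between coasts (main 0) gave 1 probe each with position as a covariate, array weights, blood cell list means and without the 4 arrays, and 1 to 6 without Beaufort_male replicate 1 (1) or replicate 2 (6), where the lone male left is assumed to vary like the other groups. Leaving out either gave 40 to 43 for the sexes, 4519 to 4647 for the coasts, 4842 to 4922 for Georgia, 9781 to 9839 for the 5 locations, 2764 to 2845 for Sarasota and 3158 to 3177 for Saint Joseph Bay.

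Of 9 calls in the gene list tests, 1 was left with an estimated correlation; fry called 3, of which 2 were among the 9, and the other 5 alternatives called 6 to 9. No paired analysis was possible because the replicate numbers only name the animals.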

Other observations

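The values below were looked at only after the data were seen, and none of them was a planned test.

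The 2 arrays of the male animal of Saint Joseph Bay had a correlation of 0.983 over probes, against a median of 0.970 (lowest 0.861, highest 0.991) for the other pairs of arrays. Probes are not independent replicates, so these correlations describe how alike the arrays are and carry no p.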
